A study of Mus musculus with 2 samples.

How the data were processed

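Chromatin from V6.5 cells, a mouse embryonic stem cell line, was immunoprecipitated with an antibody against RNA polymerase II phosphorylated at serine 5 of its C-terminal domain, a form of the enzyme found near the start of transcribed genes. Per the labels' protocols, the immunoprecipitated DNA was amplified by ligation-mediated PCR and labelled with Cy5, and input DNA from the same line was labelled with Cy3. The labels name 1 replicate, hybridised to 2 array designs that are called array 1 and array 2 here. The arrays were never averaged, because they are 2 parts of 1 replicate and not replicates of each other. The design text speaks of duplicate arrays, and a further replicate was not analysed here.

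Each deposited table paired a feature number with 1 value, and the base of its logarithm, its centring and its direction were not given in the sources used here. The deposited values were read as log2 ratios on the following evidence. Between 0 and 0.5, 4142 of the 5000 possible values with 4 decimals can arise as the base-2 logarithm of a ratio written with 5 significant digits. On both arrays exactly these 4142 values occurred and the other 858 did not, over 65490 features on array 1 and 69251 on array 2. With natural or base-10 logarithms all 5000 values can arise. The median of each array was 0, so the values had been centred on the median before deposit. The background correction, the normalization within the array, any filter on dim features and the scanner software were not given in the sources used here. These steps act on every ratio and could have changed the spread of the values and the length of both tails.

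The direction was taken as immunoprecipitated DNA over input, which is likely and not settled. Its basis is the dyes in the labels and the long tail of positive values on both arrays. If the ratio ran the other way, every count at or above 1 given here would be a count of features lower in the immunoprecipitated DNA.

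Neither the tables nor the annotation used here tied a feature number to a probe sequence, a gene or a genome position. The gene scores, the 16 gene lists (among them pluripotency genes, ribosomal protein genes, Polycomb-associated developmental regulators and fibroblast markers), the profile around transcription start sites, the agreement of neighbours on the genome and the comparison of chromosomes, all fixed before the data were examined, were therefore not run. The rule for naming genes was the 10 highest genes per array, the extremes of each list and a fixed set of stem cell and control genes, and it named none. The positions of the 3 highest values of each array were singled out after their values were seen.

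For each array, features at or above a log2 ratio of 1, that is 2-fold, were counted, and the features at or below -1 were counted as a mirror-image background. With 1 replicate no test between samples could be made and no p-value compares conditions. The depth of an array is not a count, and the single replicate, not the number of features, limits the precision. Neighbouring features on the genome report overlapping DNA fragments and are not independent, so no interval was put on the percents.

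Feature numbers were laid out on a surface of 456 columns and 534 rows, 243504 positions in all. This layout was inferred from the feature numbers without a value, whose spacing repeated at 456 more than at any other distance up to 2000 on both arrays (autocorrelation 0.0245 on array 1 and 0.0222 on array 2, with the next at 912). The surface was divided into 36 blocks of equal size, and the SD of the percent of features at or above 1 over blocks was set against 10000 random placements of those features. The column in which the 3 highest values lay was compared with 100000 random placements. Correlations between blocks were tested with 9999 permutations, which treat the blocks as independent. The spread of an array's background was taken as 1.4826 times the median distance below the median, called the lower-side SD.

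The calculations were tested on simulated arrays of 235675 and 234688 features. Their background was symmetric normal noise with the array's lower-side SD, and enriched features were shifted upward. Of the features past the threshold at which mirror-image features made up 5%, 2.23% on array 1 and 2.41% on array 2 were unenriched where 10% of features were enriched, and 0.562% and 0.375% where 25% were. These low percents rest on the symmetric background that was simulated and are no error rate for the real arrays. An estimate of the enriched share from the mode was not reported, because it gave 21.9% and 11.0% on the simulated arrays 1 and 2 with 10% enriched, and 17.6% and 12.1% with 25% enriched. Random placements were called uneven over the surface in 8 of 100 runs on array 1 and 4 of 100 on array 2, and a block raised by 3 percentage points was called in 100 of 100 runs on each. A planted column of 3 high values was found on both, but this was sure in advance, because they were set above every other value. Alternatives were another threshold, centring on the mode, scaling by the lower-side SD, centring of surface blocks and leaving out 1 column segment. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.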

Results

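Binding of RNA polymerase II phosphorylated at serine 5 was measured in V6.5 mouse embryonic stem cells by chromatin immunoprecipitation and 2-colour arrays. Serine 5 of the repeated C-terminal domain of the largest subunit is phosphorylated by the kinase of the general factor TFIIH as transcription starts, so this form marks polymerase that has begun transcription. The measurement was made in 1 replicate, spread over 2 array designs. Array 1 gave 235675 values and array 2 gave 234688 values, 470363 in all. Each value was a log2 ratio of immunoprecipitated DNA to input DNA, with this direction likely and not settled, and the median of each array was 0. The features could not be assigned to genes, so the comparisons concern classes of features and not named genes.

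The first question was how much of the probed sequence was enriched over input. On array 1, 24149 features (10.2%) lay at or above 2-fold, and 4975 (2.11%) lay at or below the mirror-image ratio. On array 2, 21436 features (9.13%) lay at or above 2-fold against 3200 (1.36%) on the low side. High features thus outnumbered their mirror image 4.85 times on array 1 and 6.70 times on array 2. With 1 replicate there was no replicate check of these counts, and the mirror-image count was taken as their background. It is not an error rate, because noise need not be symmetric and features depleted in the immunoprecipitated DNA would also be counted in it.

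High features outnumbered low ones more at 3-fold and 4-fold than at 2-fold. At or above 3-fold there were 9978 features on array 1 against 295 on the low side, and 8510 against 44 on array 2. At or above 4-fold there were 4901 features against 29 on array 1 and 3859 against 4 on array 2. The class at or above 8-fold held 481 features on array 1 (0.204%) and 271 on array 2 (0.115%), each against 1 feature on the low side. At or above 16-fold, 54 features remained on array 1 and 10 on array 2, and the low side held 0 on either array. At 1.5-fold, by contrast, the classes were poorly separated from background. The low side there held 25458 features against 45720 high ones on array 1, and 21351 against 41689 on array 2.

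Both distributions leaned to the high side. The skewness was 1.14 on array 1 and 1.17 on array 2. The 1st and 99th percentiles lay at -1.18 and 2.37 on array 1, and at -1.06 and 2.22 on array 2. The most common value lay below the median, at -0.12 on array 1 (bootstrap SD 0.015) and at -0.10 on array 2 (bootstrap SD 0.020), with the SD covering the sampling of features only. The error of this mode may be larger than the SD. On simulated arrays the enriched share taken from it was 21.9% for 10% on array 1, and 12.1% for 25% on array 2. Mirror-image features fell to 5% of those past the threshold at a log2 ratio of 1.45 on array 1, which 12403 features (5.26%) reached. On array 2 this point lay at 1.25 and was reached by 14510 features (6.18%).

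**Figure D1:**
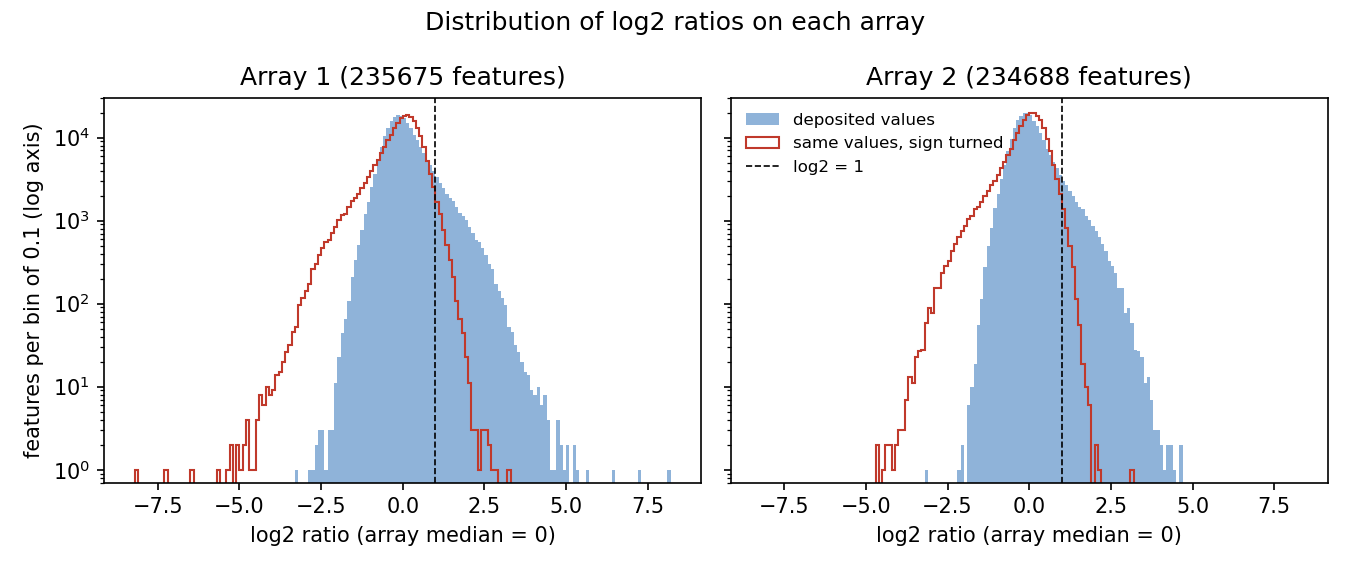
Number of features per bin of 0.1 (log axis) against the log2 ratio for array 1 (left) and array 2 (right), with the deposited values filled in blue, the same values with their sign turned as a red outline, and the 2-fold threshold dashed. Right of the threshold the filled distribution lies above the outline on both arrays, with 24149 features against 4975 on array 1 and 21436 against 3200 on array 2.

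The second comparison set the 2 arrays beside each other. They carry different designs, and whether they were normalized separately was not given, so these levels compare arrays and not conditions. The percent of features at or above 2-fold was 1.12 times as high on array 1 as on array 2, and it was higher at every common threshold, from 1.09 times at 1.5-fold through 1.26 times at 4-fold and 1.77 times at 8-fold to 5.38 times at 16-fold, where 54 features stood against 10. On the low side the ratio was 1.55 at 2-fold, 6.68 at 3-fold and 7.22 at 4-fold, the last from 29 features against 4, and at 8-fold each array held 1 low feature. The lower-side SD was 0.487 on array 1 and 0.449 on array 2. In units of each array's own SD the order of the arrays turned: 5.19% of features on array 1 and 5.32% on array 2 lay at or above 3 SD, a ratio of 0.974.

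Values at the same feature number were unrelated between the arrays. The designs differ, so a feature number need not name the same probe on both, and this lack of relation says nothing about binding. Over the 233187 positions with a value on both, Pearson's r was 0.00036 and Spearman's rho was -0.000045, across features, which are not replicates. There were 2241 positions at or above 2-fold on both arrays, where independent placement gives 2186. Positions without a value, that is feature numbers of the inferred layout absent from the deposited table, were shared far more often. Whether these positions held probes that were measured was not given. Array 1 lacked a value at 7829 positions and array 2 at 8816, of which 6328 were common, where independent placement gives 283. A value was missing on array 1 alone at 1501 positions and on array 2 alone at 2488.

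Neither the features at or above 2-fold nor those on the low side were spread evenly over the array surface. Over 36 surface blocks, the percent at or above 2-fold ran from 8.14% to 12.04% on array 1 and from 7.26% to 10.99% on array 2. The percent at or below the mirror-image ratio was also uneven, from 1.03% to 4.89% on array 1 and from 0.630% to 2.21% on array 2. For high features the SD over blocks was 0.919 percentage points on array 1, where random placements had a median of 0.372, and 0.756 on array 2, where they had a median of 0.353. For low features the SD was 0.802 points on array 1 against a median of 0.176, and 0.356 on array 2 against 0.142. None of the 10000 random placements reached the observed SD in any of these 4 comparisons (permutation p = 0.0001 each, the smallest they can give, and the same after Benjamini-Hochberg adjustment). The division into blocks was chosen after results were seen, on a layout inferred from the feature numbers, so these p-values are descriptive. The 20 blocks at the edge of the surface averaged 9.78% ± 0.876 (SD over blocks) on array 1, and the 16 inner blocks averaged 10.8% ± 0.599. On array 2 these means were 8.78% ± 0.639 and 9.58% ± 0.659. Edge blocks differed among themselves, and low percents lay mostly in the outer columns of blocks on both arrays. The highest block of array 1, at 12.04%, was an edge block in the first row of blocks. Values that touch on the surface were nearly unrelated, with r of 0.0046 between horizontal neighbours on array 1 and 0.0048 on array 2.

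The 3 highest values of array 1 lay in 1 surface column. They were 8.13, 7.25 and 6.42 on the log2 scale, in column 250 at rows 343, 347 and 346, and the highest is a ratio of 281. The next highest value of the array was 5.70. Between them, row 344 of the same column had 2.99 and row 345 had -0.05. On array 2 the highest value was 4.63, and the values at the same 5 positions ran from -0.42 to 0.77. Leaving out this column segment changed the count at or above 2-fold on array 1 from 24149 to 24145.

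**Figure D2:**
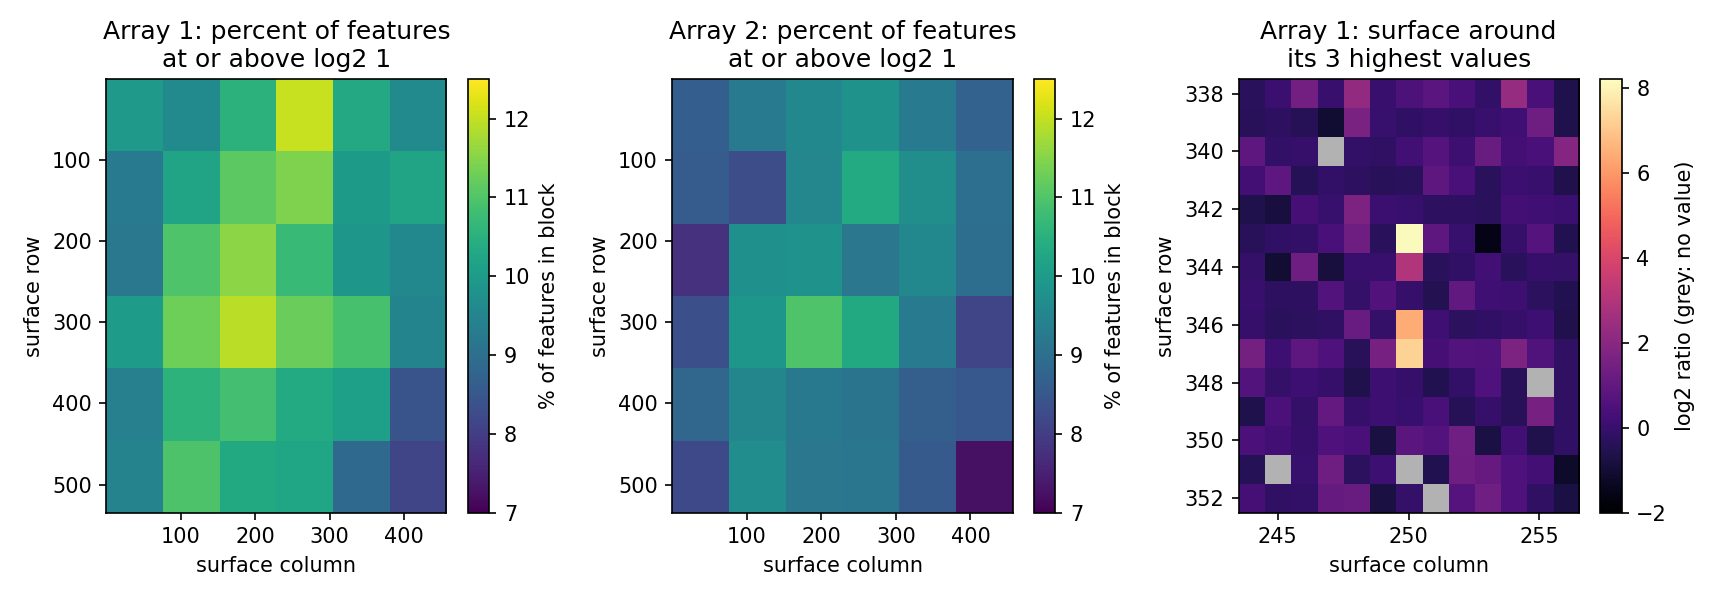
Left and middle: percent of features at or above log2 1 in each of 36 surface blocks, by surface column and row. Array 1 is on the left and array 2 in the middle, with the colour scale in percent. Inner blocks averaged 10.8% and 9.58%, above the 9.78% and 8.78% of edge blocks. Low percents lay mostly in the outer columns of blocks, and the highest block of array 1 (12.04%) was an edge block in the first row. Right: log2 ratios (colour scale) of single positions around the 3 highest values of array 1, which stand in column 250 between rows 343 and 347, with positions without a value in grey.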

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

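All results rest on 1 replicate, so no replicate could be left out, and the alternatives for genes, gene lists, positions on the genome and chromosomes were not run because features were not tied to genes. No centring gave the main counts exactly, since the median was already 0, and is no test. High features outnumbered low ones under every threshold and centring tried. Of the other 26 alternative counts, 9 stayed within 1.5 times the main count and 17 did not. At 1.5-fold the high and low counts were 45720 and 25458 on array 1 and 41689 and 21351 on array 2. At 3-fold they were 9978 and 295, and 8510 and 44. Where mirror-image features made up 5%, they were 12403 and 614 on array 1, and the low count was 697 on array 2, whose high count of 14510 stayed within 1.5 times. Past 3 lower-side SD they were 12229 and 584, and 12497 and 319. These moves follow from the stricter or looser threshold itself. Centring on the mode lowered the low counts to 3049 and 1794, as its shift of the values implies. Centring of surface blocks and leaving out the column segment, both chosen after seeing the data, kept every count within 1.5 times. The segment covers 5 positions, so leaving it out could not have moved a count that far and is no test. Its counts are nevertheless among the 9. Array 1 had the higher percent of high features at every common fold threshold, and 1.15 times that of array 2 when centred on the mode, whose place is uncertain. The order turned only where each array had its own threshold, to 0.974 past 3 lower-side SD and 0.851 where mirror-image features made up 5% (log2 1.45 on array 1, 1.25 on array 2).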

Other observations

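The tests on the column of high values and the correlation of surface blocks between arrays were chosen only after the results were seen, as was the division into surface blocks. The tests that centre or scale the blocks and the arrays were written down before their own results, although the patterns they address had been seen.

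The 3 highest values of array 1, up to 281-fold, stood in 1 column within 5 rows. Of 100000 random placements of 3 features, 0 were as tight (permutation p = 1e-05, the smallest they can give), but the column and its length were taken from these same features, on a layout inferred from the feature numbers, so this describes the tightness and leaves chance placement open. Related probes set side by side at this spot stay open: the correlation of vertical neighbours over array 1 was -0.00072, but a few positions hardly enter it. A local defect of the surface, such as a scratch or a particle, is a candidate explanation that was not tested further, because the images and the single channel intensities were not used here. No biological explanation was tested.

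The percent of features at or above 2-fold varied over the surface in nearly the same way on both arrays. Across the 36 blocks, Pearson's r between arrays was 0.836 and Spearman's rho was 0.840 (permutation p = 0.0001 each, the smallest they can give, and 0.00015 after Benjamini-Hochberg adjustment over 6 such relations), and r was 0.81 without the 2 blocks farthest from the median of array 1. The permutations treat the blocks as independent, but neighbouring blocks had similar percents, so these p-values are likely too small. An additive shift of whole blocks is argued against as the whole cause: with each block centred on its own median, the SD over blocks was still at least 1.37 times the 99th percentile of random placements. A wider background spread in some blocks would, alone, raise the high and low percents of a block together. Across blocks these percents had a Pearson's r of -0.31 on array 1 and -0.45 on array 2. This argues against a wider spread as the whole cause. As a part of the cause it stays open, because shifts of blocks move the 2 percents in opposite directions and could hide it. After each block was also scaled by its lower-side SD, the SD over blocks was at least 1.53 times that percentile. The scaling can add unevenness of its own, so this cannot decide. It raised the SD of the centred blocks from 0.770 to 0.979 points on array 1 and from 0.629 to 0.698 on array 2. Another effect of the place on the surface may remain, as may a placement of probes by class that both designs share, and neither was tested.

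Array 1 held 1.12 times the percent of 2-fold features of array 2, and after scaling by the lower-side SD 0.996 times past 2 SD, 0.974 past 3, 0.932 past 4, 0.914 past 5 and 0.9003 past 6. A wider overall spread on array 1 is a candidate explanation, but the test cannot decide it. On simulated arrays, 1.3 times as many enriched features moved the scaled ratio to 1.19 on array 1 and 1.21 on array 2 where 10% of features were enriched, but to 1.01 and 1.04 where 25% were, and the enriched share of the real arrays is not known. On the low side, array 1 held 1.03 times the percent of array 2 past 2 lower-side SD, 1.82 times past 3, 3.35 times past 4 (37 features against 11), 10.95 times past 5 (11 against 1), and 0.996 times past 6, where each array held 1 feature. A difference in the probed sequences between the designs stays open and was not tested.

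At the 1501 positions without a value on array 1 alone, the median on array 2 was -0.03, and at the 2488 positions without a value on array 2 alone, the median on array 1 was -0.02. Across the 36 blocks, the percent at or above 2-fold and the percent at or below the mirror-image ratio had a Pearson's r of -0.31 on array 1 (permutation p = 0.0637, adjusted 0.0637) and -0.45 on array 2 (permutation p = 0.0047, adjusted 0.0056). The percent at or below the mirror-image ratio averaged 2.34% ± 0.954 (SD over blocks) in the edge blocks of array 1 and 1.82% ± 0.435 in its inner blocks, and 1.45% ± 0.336 and 1.25% ± 0.358 on array 2. On array 1 both the highest block (4.89%) and the lowest (1.03%) were edge blocks. Its first row of blocks ran from 2.61% to 4.89%, its other edge blocks from 1.03% to 3.19% and its inner blocks from 1.15% to 2.59%. The higher edge mean of array 1 thus came largely from the first row and was not a trait of all edges. The first row of array 2, from 0.908% to 2.11%, lay within the range of its other blocks.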
